A study of Oryza sativa with 3 samples.

How the data were processed

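Rice leaf segments from seedlings 4 weeks old were floated for 1 day in distilled water (DW) or in 1% methanol (MeOH), and total RNA was hybridised as biotin-labelled cRNA to the Affymetrix rice array, 1 sample per array. Per the labels' protocols, cRNA was made by in-vitro transcription from cDNA primed with oligo(dT), from 6 µg of total RNA. The growth protocol names wild-type and transgenic rice, and the labels do not say which was used. The labels give 1 DW array and 2 MeOH arrays, named here MeOH 1 and MeOH 2 after the replicate numbers in their titles. Nothing in the labels says whether the MeOH samples came from separate sets of leaves, so p-values measure only the spread between these samples, which may be technical.

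The deposited files hold signal intensity for 57381 probe sets on each array, made with MAS5 in Affymetrix Expression Console 1.1 per the submitters' processing notes. The intensity values deposited are on a linear scale, and the mean of the middle 96% of each array was 500, so each array appears to have been scaled alone by the authors. Detection calls (Present, Marginal or Absent), another deposited column, were used for the DW array and for the MeOH array of the first comparison table. The authors also deposited log2 ratios to DW in 1 table per MeOH array, and for each of these a shorter table of probe sets they selected. The series' design text says that the 2 sets were normalized separately, but the DW signals of both comparison tables equalled those of the value table for the whole series in 57381 of 57381 probe sets, and so did the log2 ratios, within a tolerance of 1e-06 on the log2 scale. The values therefore gave 1 source, and a comparison with another source of values, decided on before the data were examined, was not possible.

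The table named for the second methanol comparison heads its treated columns FA, an abbreviation the labels do not explain. Its log2 ratios equalled those of MeOH 2 over DW of the value table in 57381 probe sets and those of MeOH 1 over DW in 0. The 4 columns of signals and calls headed FA match no sample label and were not used. Results of MeOH 2 are those of the array labelled as methanol replicate 2, whose treatment rests on its sample label alone.

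The 187 control probe sets were left out, and 26767 of the other 57194 were tested. The filter fixed before the data were examined asked for a Present call in the DW array or in both MeOH arrays. Calls for MeOH 2 exist only in the unused FA columns, so probe sets Present in DW or in the MeOH array of the first table were tested, a choice made after the files were seen. Log2 signals of the 3 arrays were fitted with lmFit and eBayes with a mean-signal trend in limma 3.58.1 (R 4.3.3), MeOH (n = 2) against DW (n = 1), with a two-sided Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit had 1 residual degree of freedom, and its prior was worth 5.07. The lone DW array was assumed to vary like the MeOH arrays. The prior variance followed the mean signal of all 3 arrays. A dim DW signal beside bright MeOH signals was thus given the error of a brighter probe set. Log2 ratios are given with the standard error of that fit. Where DW was not called Present, a rise is given as "at least", against the higher of the DW signal and 8.68, the lowest DW signal called Present. That value is not a detection limit, since brighter DW signals were also called Absent, such as 65.7 for Os.30657.1.S1_at. Such figures are therefore not strict lower bounds. The number of arrays limits the precision.

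In data simulated from these arrays over 26767 probe sets with 200 changed ones, limma recovered 10 of 50 probe sets raised 4-fold, 6 of 50 lowered 4-fold, 49 of 50 raised 16-fold and 21 of 50 lowered 16-fold, and called 8 unchanged ones. The changed ones were drawn only from probe sets with a DW signal above 100. Recovery of rises from dimmer DW signals was therefore not tested. In data simulated from these arrays in the same way, limma's camera called a list of 30 probe sets shifted by 1 on the log2 scale and did not call an unshifted one. Noise was drawn for each probe set alone, so this does not test lists whose members vary together. Estimated correlations of the real lists ran from -0.33 (chlorophyll breakdown) to 0.60 (tryptophan synthesis). Agreement of the MeOH arrays was set against 100 simulations of unchanged arrays that shared 1 DW array, with noise drawn from the difference between the MeOH arrays, real differences between them included. All simulated arrays started from the observed DW signals, also for probe sets that passed the filter only through MeOH 1.

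Gene lists were matched to the descriptions and symbols in the files, and 42 lists were fixed before the data were examined. The 38 lists with at least 3 tested members were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. With 1 residual degree of freedom the test with an estimated correlation has little power. Only 6353 tested probe sets had an informative description. Lists extended by the names of gene ontology molecular functions in the files (14154 tested probe sets with either) were therefore added after the files were seen. Of 3876 rice probe sets with a gene symbol or locus in the files, 2807 had a gene ID found in the reference table of the ASM3414082v1 assembly, and only 13 had an informative symbol there, so names are the files' own. The array's annotation names no genome build, so no coordinates are given.

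By the rule fixed beforehand, the named genes were the 12 largest rises and 12 largest falls past the threshold with an informative description, a Present call in the higher group where calls were used and the same direction in both MeOH arrays, 1 probe set per gene. Places not filled were given to probe sets at least 2-fold changed in both arrays, as values. Up to 4 members of each described list with the largest mean log2 ratio were added. The definition of an informative description was tightened after a first list had been seen, which removed names made only of clone codes and brought in 4 other entries.

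Alternatives planned were quantile normalization, centring on the median, log2(signal + 50), no filter, Present calls in both arrays with calls, no trend in the prior, fold minimums of 1.5 and 3, 1 probe set per gene and leaving out each MeOH array. Those chosen after seeing the data were a filter on mean signal, the removal of probe sets marked as shared between transcripts (_s_at, _x_at or _a_at), the extended lists and lists without products of plastid or mitochondrial genes. The FA columns were the only per-sample values left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.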

Results

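Methanol was tested as an elicitor on detached rice leaves: the apical 15 cm of leaves from seedlings 4 weeks old, 10 segments to a tube with 20 ml of water, were kept for 1 day with 1% methanol or without it. Transcripts were measured on 3 arrays, 1 of leaves in distilled water (DW) and 2 of leaves in methanol (MeOH 1 and MeOH 2). The protocol mentions wild-type and transgenic rice, and the labels do not say which these leaves were. The median MAS5 signal was 40.7 on the DW array, 38.7 on MeOH 1 and 44.0 on MeOH 2. A Present call, the software's statement that a transcript was detected, was given to 43.1% of probe sets on the DW array and to 44.2% on MeOH 1. The control probe set at the tail end of the actin transcript exceeded the one at its start by a log2 ratio of 3.59 on DW. The value was 3.31 on MeOH 1 and 3.54 on MeOH 2. Signal was thus much stronger at the tail end on all 3 arrays, and the cause was not tested. The comparison table of the array labelled methanol replicate 2 heads the treated columns FA and not MeOH, so the treatment of MeOH 2 rests on its sample label. The bacterial and phage hybridisation spikes, added in equal amounts by the standard procedure, were lower on MeOH 1 than on DW by a median log2 ratio of -0.64 and differed little on MeOH 2 (-0.08).

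The first comparison asked which transcripts differed between methanol and water after 1 day. In limma's test 379 of 26767 probe sets were higher in methanol and 1 was lower. The 379 rises had a median log2 ratio of 3.19, a 9.15-fold change, with DW signals taken as measured, and 112 of them had no Present call in water. The p-values of these 112 do not take in the larger error of a dim DW signal. Every one of the 379 was at least 2-fold higher in both MeOH arrays. At an unadjusted p under 0.05 there were 1879 higher and 1344 lower probe sets.

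Among the largest named rises was a putative ethylene response factor ERF1 (Os.30670.1.S1_at), of a family of transcription factors. Its signal was 13.1 in DW, 1550 in MeOH 1 and 872 in MeOH 2, at least 88.5-fold higher (adjusted p = 0.00256). A putative cytochrome P450 (Os.33102.1.S1_at), of a family of oxygenases, rose 58.5-fold, to 5046 and 5492 (log2 ratio 5.87 ± 0.21 SE, adjusted p = 0.000970). A ribosomal L40e family member (Os09g0452700) was at least 144-fold higher, with signals of 4.07 in DW, 1031 in MeOH 1 and 1507 in MeOH 2 (adjusted p = 0.00105). A further P450 (OsAffx.20305.1.S1_at) rose at least 34.8-fold, with 577 in MeOH 1 and 158 in MeOH 2, and a putative elongation factor 2 (Os.32865.1.S1_at) at least 51.2-fold. An aminotransferase-like transcript (Os.2821.1.A1_at) rose at least 41.7-fold (880 in MeOH 1 and 149 in MeOH 2), the peroxidase POC1 (Os.57547.1.S1_at) at least 36.8-fold (737 and 138), a tRNA isopentenyl transferase-like transcript (OsAffx.14808.1.S1_at) at least 27.4-fold and a relative of the homeobox protein PpHB4 (OsAffx.15983.1.S1_at) at least 45.0-fold. The other 3 of the 12 were glutathione S-transferases. The only transcript that fell past the threshold was the expansin Os-EXPA2 (Os.4644.1.S1_at), a cell wall loosening protein, from 1344 to 355 and 457 (log2 ratio -1.74 ± 0.27, adjusted p = 0.0461). All 379 calls rest on the trend of the prior variance on mean signal, without which limma called 0 higher and 0 lower (1691 and 741 at an unadjusted p under 0.05). Quantile normalization left 164 higher and 0 lower calls, and Os-EXPA2, P450 OsAffx.20305.1.S1_at, POC1 and the aminotransferase-like transcript then missed the threshold (adjusted p from 0.0966 to 0.112). These also missed it with log2(signal + 50) (adjusted p from 0.0555 to 0.241) and with no filter (0.0504 to 0.0638). Sizes of rises from dim DW signals are uncertain. With log2(signal + 50) the log2 ratio was 3.04 for the aminotransferase-like transcript, against 7.35. For the tRNA isopentenyl transferase-like one it was 2.45 against 6.54, and for the L40e member 4.58 against 8.26.

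**Figure D1:**
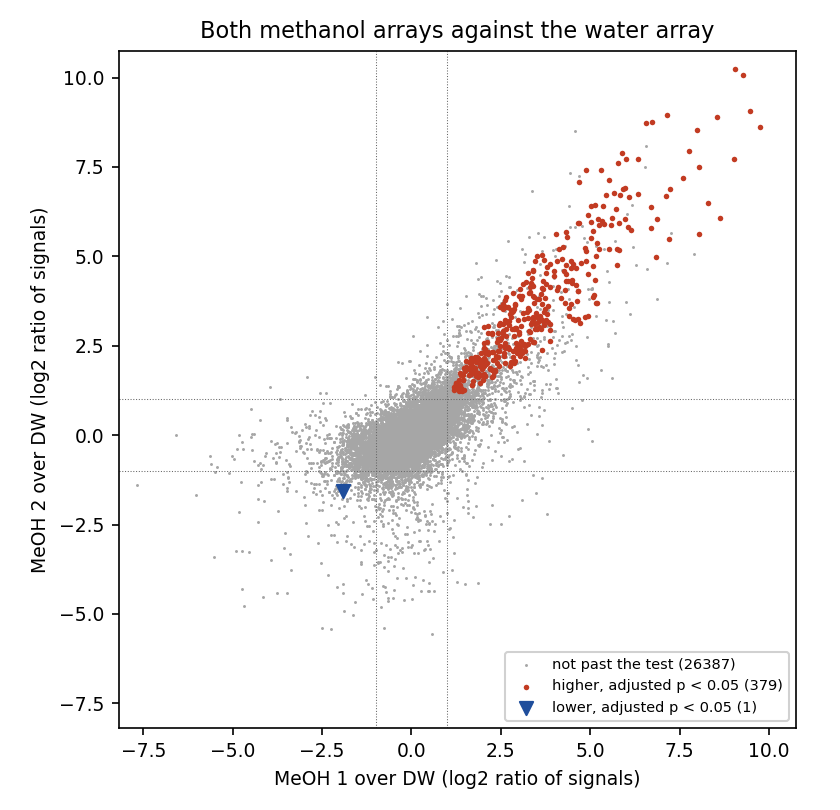
Log2 ratio to the DW array of each of the 26767 tested probe sets in MeOH 1 (horizontal axis) and in MeOH 2 (vertical axis). Red points are the 379 probe sets that were higher and the blue triangle the 1 that was lower at an adjusted p under 0.05 in limma's test, and dotted lines mark 2-fold changes.

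The other 11 places for falls were filled by probe sets at least 2-fold lower in both MeOH arrays that did not pass the test, most of them dim. The putative lipase homolog Os.33319.1.S1_at had a signal of 75.9 in DW, 4.26 in MeOH 1 and 3.30 in MeOH 2 (adjusted p = 0.284), and a short-chain dehydrogenase-reductase (OsAffx.4094.1.S1_at) had 106, 9.44 and 4.94. A putative endo-1,4-beta-xylanase X-1 (Os.36438.1.S1_at) had 52.3, 4.96 and 5.25, and a mitogen-activated protein kinase 3 (Os.57513.1.S1_at) 18.2, 1.53 and 2.06. A putative nucleoid DNA binding protein (Os.6792.1.S1_at) had 394, 107 and 99.2 (adjusted p = 0.0802), and beta-glucosidase isozyme 2 (Os.11510.1.S1_at) 104, 30.1 and 29.0. The remaining ones were annotated as a lectin, a gag-pol polyprotein, an Sm-like protein, a glycine-rich protein and an alcohol dehydrogenase, with DW signals from 26.1 to 79.5.

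Transcripts of tryptophan synthesis were higher in methanol. Of 10 tested members matched by description, 3 rose past the test over all probe sets and 4 adjusted over the list alone, none fell, and the list median was a log2 ratio of 0.65 (camera, adjusted p = 7.48e-05, with an adjusted p = 0.669 with an estimated correlation). Anthranilate synthase alpha 2 (Os.7114.1.S1_s_at), which makes anthranilate from chorismate, rose from 608 in DW to 6532 and 3723 (log2 ratio 3.02 ± 0.34, adjusted p = 0.0160). The tryptophan synthase beta subunit (Os.57472.1.S1_x_at), of the last step, rose from 1047 to 8957 and 5195 (log2 ratio 2.70 ± 0.33, adjusted p = 0.0208). Phosphoribosylanthranilate isomerase (Os02g0266000) rose from 819 to 4330 and 3319 (log2 ratio 2.21 ± 0.24, adjusted p = 0.0132). An indole-3-glycerol-phosphate synthase probe set (Os.17629.1.A1_at) had 5979, 14878 and 12125 (adjusted p = 0.0755). Without probe sets shared between transcripts, a setting chosen after seeing the data, the list missed the threshold (median 0.33, adjusted p = 0.140).

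Extended after the files were seen by probe sets annotated only with the enzyme's molecular function, the tryptophan list had 24 tested members. Of these 12 rose past the test over all probe sets, 14 adjusted over the list alone and none fell, with a median log2 ratio of 1.55 (adjusted p = 2.85e-15, with an adjusted p = 0.713 with an estimated correlation). A probe set with indole-3-glycerol-phosphate synthase activity (Os.50903.1.S1_at) rose from 224 to 14950 and 12725 (log2 ratio 5.94 ± 0.20, adjusted p = 0.000970). A further probe set with a closely related ID (Os.50903.2.S1_at, Os09g0255400), which may be of the same gene, was at least 93.1-fold higher. A probe set with tryptophan synthase activity (Os.32503.1.S1_at) rose from 695 to 9659 and 7215. A putative phosphoribosylanthranilate transferase (Os.26406.2.S1_x_at) rose 5.64-fold (adjusted p = 0.0297). Downstream, the list of tryptophan-derived amines had 1 tested member by description and was not tested as a list. The member matched by description, an aromatic-L-amino-acid decarboxylase (OsAffx.5702.1.S1_s_at), of the enzymes that turn aromatic amino acids into amines, rose from 866 to 9912 and 6812 (log2 ratio 3.25 ± 0.27, adjusted p = 0.00564). A probe set matched only by its tyrosine decarboxylase activity (Os.49621.1.S1_at) had 652, 290 and 384 (log2 ratio -0.97, adjusted p = 0.282).

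**Figure D2:**
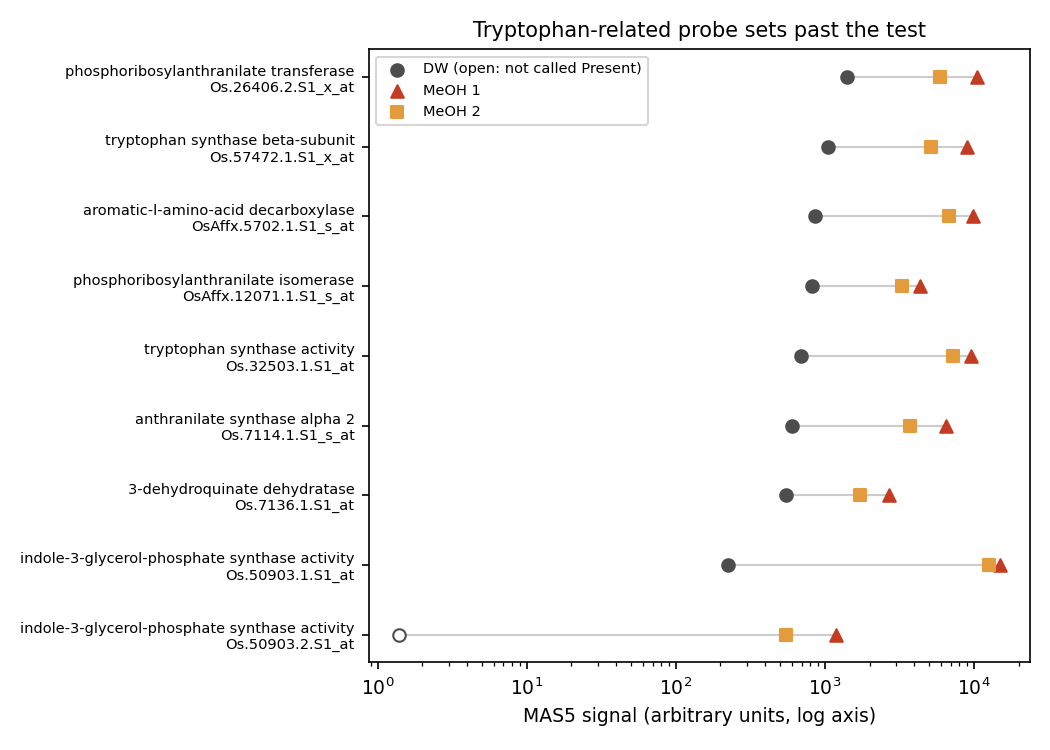
MAS5 signal (log axis) of the named tryptophan, amine and shikimate probe sets that rose past the test, with DW as circles (open where not called Present), MeOH 1 as triangles and MeOH 2 as squares. Both MeOH signals lie above the DW signal in each row, as for anthranilate synthase alpha 2 with 608 in DW and 6532 and 3723 in methanol.

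The shikimate pathway, which supplies chorismate for the aromatic amino acids, had 10 tested members with a median log2 ratio of 0.98. One rose past the test over all probe sets, and 6 rose and 0 fell adjusted over the list alone (camera, adjusted p = 0.000342, and adjusted p = 0.669 with an estimated correlation). The transcript past the test was a putative 3-dehydroquinate dehydratase (Os.7136.1.S1_at), which rose from 551 to 2693 and 1719 (log2 ratio 1.97 ± 0.31, adjusted p = 0.0463). EPSP synthase (3-phosphoshikimate 1-carboxyvinyltransferase) had 1616, 4278 and 3577 on 1 probe set (Os06g0133900, adjusted p = 0.0550) and 2003, 5143 and 4423 on another (adjusted p = 0.0528). A phospho-2-dehydro-3-deoxyheptonate aldolase (Os.22631.1.S1_a_at), of the entry step, had 4181, 9312 and 7767 (adjusted p = 0.103). The 2 tested members for phenylalanine and tyrosine synthesis had log2 ratios of 0.26 and 0.19 and did not pass (adjusted p = 0.69 and 0.80). The shikimate median was 0.43 with no filter, and 0.40 over the 21 members of the list extended by molecular function, of which 8 rose and 2 fell adjusted over the list alone (adjusted p = 0.00559, and adjusted p = 0.713 with an estimated correlation).

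Glutathione S-transferases, which couple foreign and reactive compounds to glutathione, were higher in methanol. Of 56 tested probe sets 16 rose past the test and 0 fell, 27 rose and 2 fell adjusted over the list alone, and the median log2 ratio was 1.09 (camera, adjusted p = 4.26e-22, and adjusted p = 0.669 with an estimated correlation). Os.9013.1.S1_at rose from 287 in DW to 10790 and 19021 (log2 ratio 5.64 ± 0.34, adjusted p = 0.00202), and OsGSTU12 (Os.13015.1.S1_at) from 248 to 7374 and 8754 (5.02 ± 0.21, adjusted p = 0.000970). OsGSTU5 (Os.4759.1.S1_at) was at least 52.7-fold and Os.40662.1.S1_at at least 64.9-fold higher. Among probe sets Present in both arrays with calls, which leaves out members not detected in water, the list median was 0.56, with the list still past the threshold (adjusted p = 3.65e-16).

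Other families of detoxification held strong rises, but their lists did not pass the list test. Cytochrome P450 had 90 tested probe sets with 6 rises past the test, and 18 rises and 6 falls adjusted over the list alone (median -0.05, 0.08 in MeOH 1 and -0.09 in MeOH 2, adjusted p = 0.158). A further P450-like transcript (Os.25621.2.S1_at) rose from 911 to 11270 and 8626. UDP-glycosyltransferases had 3 rises among 41 (median 0.12, -0.06 in MeOH 1 and -0.13 in MeOH 2, adjusted p = 0.125), with a putative salicylate-induced glucosyltransferase (Os.12253.1.S1_at) from 301 to 6675 and 8863 (log2 ratio 4.68 ± 0.24, adjusted p = 0.00124). The ABC and MATE transporter list had 4 rises among 39 (median -0.07, adjusted p = 0.340), 1 of them (Os.38812.1.S1_at) matched by a weak similarity and annotated as a serine-type endopeptidase inhibitor. A MATE efflux family transcript (OsAffx.26254.1.S1_at) rose 21.4-fold, and the ABC transporter PDR9 (Os.467.1.S1_a_at) 4.30-fold.

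Pathogenesis-related transcripts, made in leaves under attack by microbes, were higher, with 5 rises and 0 falls among 57 tested, 16 rises and 1 fall adjusted over the list alone and a median log2 ratio of 0.66 (camera, adjusted p = 2.71e-08, and adjusted p = 0.669 with an estimated correlation). Chitinase IIb (Os.7991.1.S1_at), which cuts fungal cell walls, rose from 60.6 to 2218 and 781 (log2 ratio 4.44 ± 0.59, adjusted p = 0.0266). The thaumatin-like protein TLP7 (Os12g0630200) rose from 89.4 to 3181 and 1159 (adjusted p = 0.0231), and a putative pathogenesis-related protein precursor (Os.13965.1.S1_at) from 133 to 3191 and 1246 (adjusted p = 0.0278). The chitinase MIRCH1 (Os10g0542900) had 6.64, 298 and 37.4 and did not pass. The list median was 0.86 in MeOH 1 and 0.39 in MeOH 2. It was 0.40 with log2(signal + 50) and 0.38 among probe sets Present in both arrays with calls, with the list past the threshold in both.

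Lists of signalling and of low-oxygen markers rose too, each with adjusted p = 0.669 with an estimated correlation. AP2/ERF factors had 2 rises among 28, and 4 adjusted over the list alone (median 0.37, camera, adjusted p = 0.000460). The AP2 factor EREBP (Os.8920.1.S1_at) had 14.1, 145 and 354 (adjusted p = 0.0502). Jasmonate synthesis and JAZ had 3 rises among 12, and 3 adjusted over the list alone (median 0.32, adjusted p = 0.00571), with medians of 0.78 in MeOH 1 and 0.06 in MeOH 2. Its lipoxygenase CM-LOX2 (Os.13008.1.S1_at), of the first step of jasmonate synthesis, rose from 136 to 1941 and 1225 (adjusted p = 0.00838), and the locus Os06g0215600, without a description in the files, at least 6.67-fold (adjusted p = 0.0453). Receptor-like kinases had 2 rises among 136, a share close to that over all tested probe sets (379 of 26767). Adjusted over the list alone 4 rose (median 0.18, adjusted p = 0.00874), with medians of 0.29 in MeOH 1 and 0.08 in MeOH 2. Of the kinases OsAffx.2516.1.S1_at rose at least 10.6-fold. The hypoxia markers had 3 rises among 12, and 5 adjusted over the list alone (median 0.43, adjusted p = 7.48e-05), with medians of 0.69 in MeOH 1 and 0.25 in MeOH 2. Among them were the oxygen-binding hemoglobin 1 (Os.12191.1.S1_s_at), at least 14.4-fold higher (adjusted p = 0.0440) and hemoglobin 2 (Os.12163.1.S1_at), at least 13.9-fold higher (adjusted p = 0.0447). A pyruvate decarboxylase (Os.1445.1.S1_at) had 1208, 3359 and 2466 (adjusted p = 0.0999) and alcohol dehydrogenase 2 (Os.8815.1.S1_at) 102, 206 and 110 (adjusted p = 0.744). A dim alcohol dehydrogenase that the hypoxia list did not hold (Os11g0210300) went the other way, with 38.6, 10.3 and 2.16 (limma, adjusted p = 0.539). These 4 lists missed the threshold among probe sets Present in both arrays with calls (adjusted p of 0.327 for AP2/ERF, 0.487 for jasmonate, 0.145 for the kinases and 0.126 for hypoxia), and the jasmonate median was then -0.01. The kinases missed it with no filter too (median 0.06, adjusted p = 0.335). In both settings the AP2/ERF median was 0.17 and the hypoxia median 0.24, though with no filter these lists still passed (adjusted p = 0.0408 and 0.0124).

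WRKY factors, regulators of defence genes, had 2 rises among 24 and 6 adjusted over the list alone, and passed the list test (adjusted p = 0.0185, and adjusted p = 0.669 with an estimated correlation). Their median log2 ratio was only 0.01 (0.19 in MeOH 1 and 0.10 in MeOH 2) and turned negative under quantile normalization (-0.01), among other settings. Of 10000 random lists of like mean signal, 76.9% had a lower median. The list missed the threshold with no filter (adjusted p = 0.394), with the filter on mean signal (0.0967) and without probe sets shared between transcripts (0.415). A WRKY50-like factor (OsAffx.14605.1.S1_s_at) rose from 319 to 1247 and 1031 (adjusted p = 0.0278), whereas WRKY5 (Os.30657.1.S1_at) had 65.7, 1040 and 263 and WRKY8 (Os.31521.1.S1_at) 191, 460 and 1587, and neither passed. Alcohol and aldehyde dehydrogenases had 1 rise among 40, and 4 adjusted over the list alone (median 0.19, adjusted p = 0.0486, and adjusted p = 0.697 with an estimated correlation). The median was 0.35 in MeOH 1 and 0.09 in MeOH 2. The member that rose, an aspartate-semialdehyde dehydrogenase (OsAffx.18503.1.S1_at), is an enzyme of amino acid synthesis and not one of alcohol breakdown. This list missed the threshold in several settings, such as log2(signal + 50) (adjusted p = 0.0624), and its median was -0.02 with no filter.

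Photosynthesis transcripts were lower as lists, with no single member past the test over all probe sets. Photosystem and light-harvesting transcripts had a median log2 ratio of -0.44 over 38 tested, with 0 rises and 0 falls adjusted over the list alone (camera, adjusted p = 1.36e-05, and adjusted p = 0.669 with an estimated correlation). The median was -0.71 in MeOH 1 and -0.23 in MeOH 2. The 22 kDa protein of photosystem II (Os.175.1.S1_at) had 8892 in DW, 1877 in MeOH 1 and 4620 in MeOH 2, and a photosystem I subunit II (Os.7974.2.S1_at) 723, 263 and 410. MeOH 1 was the array with the lower hybridisation spikes. On it the 120 tested probe sets of the plastid genome had a median log2 ratio to DW of -0.96, against -0.05 in MeOH 2. Without its 15 probe sets described as products of plastid genes, a setting chosen after seeing the data, the photosystem list had a median of -0.43 (-0.61 in MeOH 1 and -0.27 in MeOH 2; adjusted p = 0.000388, and adjusted p = 0.692 with an estimated correlation). Calvin cycle transcripts, of carbon fixation, had a median of -0.43 over 19, with 0 rises and 2 falls adjusted over the list alone (adjusted p = 0.000709, and adjusted p = 0.669 with an estimated correlation). Fructose-1,6-bisphosphatase (Os.3408.1.A2_a_at) had 4850, 2378 and 2514 (adjusted p = 0.0933). A probe set for the Rubisco large chain (OsAffx.26050.37.S1_s_at) had 9398, 3276 and 11273. Without the 3 probe sets for that chain the list median was -0.33 (adjusted p = 0.000838, and adjusted p = 0.692 with an estimated correlation). Without probe sets shared between transcripts the Calvin cycle list missed the threshold (median -0.47, adjusted p = 0.102).

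**Figure D3:**
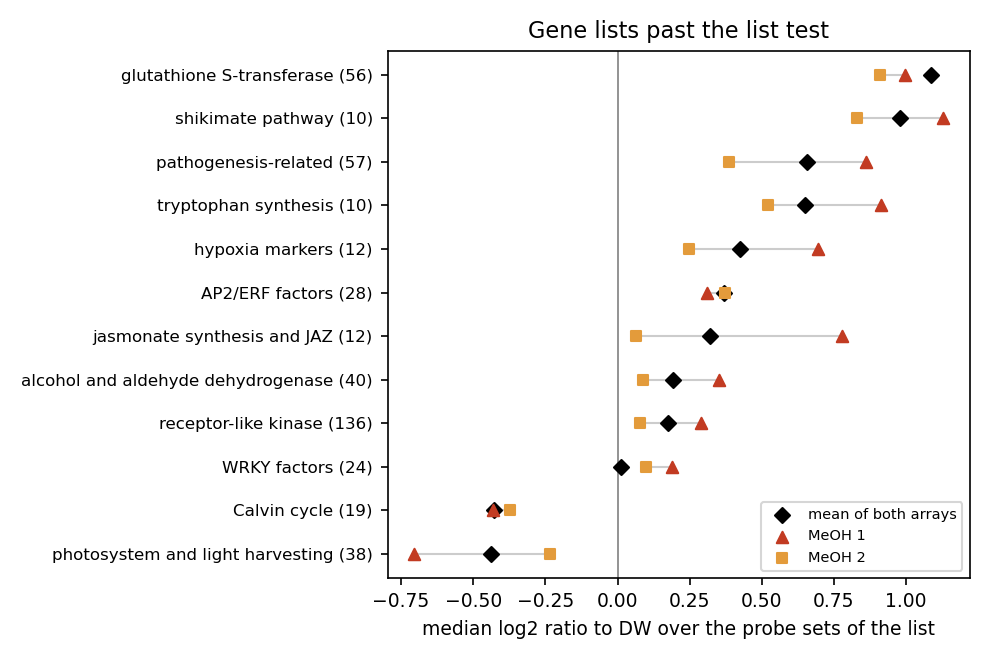
Median log2 ratio to DW over the tested probe sets of each gene list past the list test, for the mean of both arrays (diamonds), MeOH 1 (triangles) and MeOH 2 (squares), with the number of probe sets in parentheses. Glutathione S-transferases have a median of 1.09 and the photosystem list one of -0.44, with -0.71 in MeOH 1 and -0.23 in MeOH 2.

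The other 26 lists did not pass the list test. The medians of some still lay far out among 10000 random lists of like mean signal. The share of random lists with a lower median was 99.99% for proteasome and ubiquitin ligases and 0.11% for cell wall loosening. Others lay near the middle, such as peroxidases with 51.3%. Senescence and autophagy transcripts had 0 calls among 19 (median log2 ratio -0.08, adjusted p = 0.930), and chlorophyll breakdown had a median of -0.58 over 3 members, with 2 falls adjusted over the list alone. Methanol and one-carbon metabolism had 0 calls among 6 (median 0.05), and the formate dehydrogenase (Os.4156.1.S1_at) had 4086, 4538 and 3984. Cell wall loosening had a median of -0.35 over 28, with 1 rise, the beta-expansin EXPB4 (Os06g0219500) from 547 to 2219 and 3272, and 1 fall. Nitrogen remobilisation had a median of -0.36 over 16 (adjusted p = 0.0507) and chlorophyll synthesis -0.30 over 5. Phenylpropanoid and lignin transcripts had 0 calls among 26 (median -0.20). Medians were -0.29 for NAC factors, -0.06 for MYB factors, -0.16 for ethylene synthesis, 0.04 for abscisic acid and dehydration, -0.16 for auxin and 0.06 for cytokinin response. NAC factors had 0.20 in MeOH 1 and -0.29 in MeOH 2, MYB factors 0.03 and -0.07, and ethylene synthesis -0.57 and 0.14. Medians over both arrays were -0.06 for peroxidases (-0.17 and 0.03), -0.05 for antioxidant enzymes, -0.04 for ribosomal proteins, 0.09 for proteasome and ubiquitin ligases and 0.02 for heat shock proteins and chaperones. Markers of other tissues had medians of -0.26 for the epidermis, -0.37 for vascular tissue, -0.09 for dividing cells and 0.18 for roots. The epidermis markers had -0.40 in MeOH 1 and -0.14 in MeOH 2, and the vascular ones -0.45 and -0.09. The reference genes had a median of -0.14 with 0 calls among 48. The diterpenoid phytoalexin list had 2 tested members and was not tested, and the fungal and bacterial control probe sets were left out of the tests.

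The second comparison counted probe sets at least 2-fold changed against DW in each array, for which there is no test. In both MeOH arrays 1260 probe sets were at least 2-fold higher and 318 at least 2-fold lower. With those shared by both arrays included, MeOH 1 had 2042 higher and 1563 lower, and MeOH 2 had 1652 and 854. The filter used calls of MeOH 1 and none of MeOH 2, which limits a comparison of these counts between the arrays. Independent lists of these sizes would share 126 and 49.9. Since both ratios have the same DW array below the line, simulated unchanged arrays gave 420 higher (363 to 477) and 418 lower (371 to 472). The simulation starts from DW signals, also for probe sets that passed the filter only through MeOH 1, which could hardly fall in the real data. The same filter let in probe sets not detected in DW because MeOH 1 was bright, which favours rises, and the simulation made no such selection. Neither the higher nor the lower count is therefore interpreted against the simulated one. With log2(signal + 50) the counts were 752 and 65, and among probe sets Present in both arrays with calls 659 and 144. With no filter they were 5634 and 3885, and at 1.5-fold 2183 and 1447.

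The last comparison asked how alike the MeOH arrays were. Across the 26767 probe sets, which are not independent replicates, their log2 ratios to DW had a Pearson r of 0.74 (0.50 in simulated unchanged arrays that shared 1 DW array) and a Spearman rho of 0.64 (0.46 simulated). The covariance was 0.57 against 0.21 simulated, a difference of 0.36. The direction was the same for 74.4% of probe sets (66.6% simulated). With 1 DW array the control could not be split, so part of the agreement may come from that shared array. These simulated values too start from DW signals, dim ones included. In the authors' deposited tables of selected probe sets, the first held 2043 higher and 1563 lower and the second, headed FA, 1806 higher and 692 lower. The authors' deposited tables had 1367 probe sets in common, 1038 higher in both, 313 lower in both and 16 of opposite direction.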

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

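The filter on mean signal, the removal of probe sets shared between transcripts, the extended lists and the lists without products of organelle genes were chosen after the data were seen. The number of probe sets called higher by limma, 379, became 164 with quantile normalization, 240 among probe sets Present in both arrays with calls and 0 without the trend in the prior (smallest adjusted p 0.120, 1691 higher at an unadjusted p under 0.05). All 164 and all 240 were among the 379, and under centring, log2(signal + 50), no filter and both added settings the count stayed within 1.5 times. The single lower call became 0 under quantile normalization, centring, log2(signal + 50), no filter, Present calls in both arrays and no trend (from 741 to 1976 at an unadjusted p under 0.05), and 9 without shared probe sets. The cause was not tested. The counts at least 2-fold higher and lower, 1260 and 318, became 752 and 65 with log2(signal + 50), 5634 and 3885 with no filter, 659 and 144 with Present calls in both arrays, 2183 and 1447 at 1.5-fold and 739 and 67 at 3-fold. Leaving out 1 MeOH array left 1 array against 1, with no test, and gave 1652 to 2042 at least 2-fold higher and 854 to 1563 lower. The correlation of the MeOH arrays was 0.55 with no filter. Lists past the test, 10 higher and 2 lower, became 6 higher with Present calls in both arrays, 1 lower without shared probe sets, and 0 and 0 with an estimated correlation. The WRKY median reversed under quantile normalization (-0.00876), no filter (-0.0728), Present calls in both arrays (-0.0386), the filter on mean signal (-0.107) and without shared probe sets (-0.114). The alcohol and aldehyde dehydrogenase median reversed with no filter (-0.0186) and the jasmonate median with Present calls in both arrays (-0.0094). The causes were not tested. No paired analysis was possible because water had 1 array, so the groups share fewer than 2 replicate numbers. The spread between MeOH arrays limits dim probe sets: it was 1.06 on the log2 scale per array at signals from 10 to 30 and 0.25 above 3000. Below that range it was 2.27 at signals from 6 to 10 and 2.4 from 2 to 6.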

Other observations

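The gene ontology molecular functions in the files were tested after the data were seen, 235 terms with at least 10 tested probe sets, of which 7 were higher and 4 lower with camera, and none with an estimated correlation (adjusted p = 0.995). Chitinase activity had a median log2 ratio of 1.27 over 28 probe sets (adjusted p = 1.07e-10), 1.42 in MeOH 1 and 0.98 in MeOH 2, and 5 of its probe sets rose past limma's test. Dioxygenases had 7 rises among 37 (median 0.26, adjusted p = 0.00158), with medians of 0.68 in MeOH 1 and 0.29 in MeOH 2. Hexosyl transferases had 14 among 111 with a median of only 0.04 (adjusted p = 0.00158), 0.10 in MeOH 1 and 0.06 in MeOH 2. Serine endopeptidase inhibitors had 2 rises among 23 (median 0.27, adjusted p = 0.00436), with medians of 0.46 in MeOH 1 and 0.18 in MeOH 2. Rubisco activity was lower (median -0.47 over 14, adjusted p = 0.0184, -0.55 in MeOH 1 and -0.32 in MeOH 2), and so was chlorophyll binding (median -0.59 over 11, adjusted p = 0.0398), with -0.95 in MeOH 1 and -0.22 in MeOH 2.

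In the lists extended by these functions, single enzymes of several pathways stood out, named after their values were seen. A probe set with formate dehydrogenase activity (Os.14187.1.S1_at), of the last oxidation step of methanol in plants, had 349 in DW and 7375 and 3544 in methanol (log2 ratio 3.87 ± 0.42, adjusted p = 0.0133). The probe set described as formate dehydrogenase (Os.4156.1.S1_at), given above, changed little. One with glycine hydroxymethyltransferase activity (Os.25477.1.S1_at) rose from 244 to 932 and 945 (adjusted p = 0.0202). One with prephenate dehydratase activity (Os.5186.1.S1_at), on the way to phenylalanine, rose from 591 to 2455 and 1859 (adjusted p = 0.0271), and a 12-oxophytodienoic acid reductase (Os.8778.1.S1_a_at), of jasmonate synthesis, from 527 to 5587 and 9496 (adjusted p = 0.00676). Among the extended lists, alcohol and aldehyde dehydrogenases no longer passed (median 0.05 over 52, adjusted p = 0.129), and the other 11 lists that had passed by description still did, though none with an estimated correlation (adjusted p = 0.713). The extended one-carbon list as a whole did not pass (median -0.12 over 24, adjusted p = 0.954).

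The tests of scaling, of power, of other splits, of shared probe sets, of dim signals and of plastid transcripts against random lists were chosen after the result was seen, while the settings used for scaling and dim signals had been planned. Higher calls outnumbered lower ones 379 to 1. Under quantile normalization, which left 164 calls, 1217 probe sets were at least 2-fold higher and 340 lower in both arrays, a ratio of 3.58 (3.96 with 1251 and 316 under centring), so array scaling is unlikely to be the whole cause. The test finds falls less often than rises in simulated data. Among 12604 probe sets with the DW signal and the mean MeOH signal both above the median DW signal, 172 were at least 2-fold higher and 23 lower in both arrays. This ratio of 7.48 makes low power unlikely to be the whole cause. Since the cut held for both groups, a DW signal just above it could count only as a rise. A mean MeOH signal just above it could count only as a fall. The excess was smaller at 1.5-fold (2183 higher and 1447 lower) and with no filter (5634 and 3885). The 3 splits of the arrays are too few for a share under 0.05; 1 split, the real one with 380 calls, gave that many, and the highest other gave 0 (1603 at an unadjusted p under 0.05). A methanol response and a deviation of the lone DW array, which would show in both ratios, both stay open.

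Glutathione S-transferase transcripts may have risen through several genes and not through 1 bright transcript read by related probe sets: the 40 members on probe sets not marked as shared had a median log2 ratio of 1.09 (quartiles 0.25 and 2.60), and 13 of them rose past the test. Probe sets of that kind can still bind close relatives, so cross-hybridisation is weakened only for the list as a whole. Dim DW signals may account for part of the size, since the median with log2(signal + 50) was 0.76 against 1.09, but are unlikely to be the whole cause, since the call held. A methanol response and the lone DW array both stay open.

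Transcripts of the plastid genome were lower in MeOH 1 than in MeOH 2, in 95% of 120 probe sets. Their median log2 ratio was -0.87, and lay 0.86 under that of random probe sets of like signal (a difference of -0.86, random lists -0.087 to 0.071). This argues against a scaling or brightness effect shared by all probe sets of like signal. Scaling each array to the same mean keeps such lists level, so array effects on only part of the probe sets were not tested by them. The 32 tested probe sets of the mitochondrial genome were also lower in MeOH 1 (median -0.36, against -0.21 to 0.25 in random lists). Less carry-over of RNA without a poly(A) tail would give this, but the Bacillus labelling spikes, which have tails, were lower by a median of -0.32 too, the hybridisation spikes by -0.55 and ribosomal RNA by -0.27, so it stays open. A difference between the leaves, or in what the array whose column is headed FA received, was not tested and stays open.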
